A study of Rattus norvegicus with 4 samples.

How the data were processed

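Single-nucleus RNA profiles of 4 male Sprague Dawley rats of about 400 g were used. Per the labels' protocols, each animal received GDF15 at 100 µg/kg intraperitoneally, tissue was taken 6 hours later, 3 punches holding the area postrema and both sides of the nucleus tractus solitarius were pooled per animal, and nuclei were captured with a droplet-based 3' assay. Each library is 1 animal. All 4 animals belong to 1 group, so no effect of the injection was tested and every test compares sets of nuclei within the same animals.

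The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised. Per the submitters' processing notes Cell Ranger 3.1 and the rat build Rnor_6.0 were named, and the matrix headers give software version 3.1.0. Whether reads in introns were counted is not given in the sources used here. Each matrix holds 32883 genes and 6794880 barcodes, that is, the authors deposited it before any selection of nuclei. Gene symbols and Ensembl identifiers are those that the files pair with each other. The gene table of another assembly that was supplied was not used. Overlapping genes and close paralogs cannot be separated further in these counts.

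Total UMIs per library were 118399243, 91585241, 60481844 and 100312785 in replicates 1, 2, 3 and 4. A barcode was taken as a nucleus with at least 1000 UMIs, at least 500 genes and at most 5% mitochondrial UMIs, and with a profile that departed from the pooled profile of barcodes of at most 100 UMIs (Monte Carlo multinomial test with 10000 draws, false discovery rate 0.001; barcodes of 10000 UMIs or more were kept without this test). Of 32785, 18233, 10594 and 23986 barcodes past the UMI and gene minimum, 4785, 6441, 7278 and 9475 were also under the mitochondrial limit, so this limit removed more barcodes than the profile and doublet steps in each library. The profile test then kept 4784, 6432, 7278 and 9362. Barcodes of at least 100 and under 1000 UMIs had a median of 764, 594, 366 and 701 UMIs, so the minimum of 1000 lies close to the plateau of barcodes without a nucleus in replicates 1 and 4. Barcodes of at most 100 UMIs lie below that plateau. In replicate 1, for example, UMIs fell from 592 at rank 71552 to 39 at rank 79279. The profile test thus did not compare barcodes with the plateau, and cannot show that those kept held a nucleus. Doublets were scored against simulated pairs of nuclei within a library and the highest scores were removed at 0.8% per 1000 nuclei, which left 4601, 6101, 6854 and 8661 nuclei. Called nuclei had medians of 3481, 3305, 2174 and 2297 UMIs. Counts were compared between libraries to look for one deposited more than once, and the lowest chi-square per degree of freedom of any pair was 122, so none were merged.

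Counts were scaled to the same total per nucleus and log-transformed. The 2000 most variable genes were z-scored within each animal and reduced to 30 principal components, and a graph of 20 neighbours was partitioned with Leiden at resolution 1.0, which gave 48 clusters. The 167 genes of the 8 gene lists, mitochondrial genes and ribosomal protein genes were left out of the clustering, so that listed genes could be compared between clusters. Of those genes 2 (Gfra1 and Hspa1a) were not among the symbols, nor were 5 of the 132 cell type markers (Lhfpl3, Dock2, Pecam1, Col1a2 and Foxj1). A cluster of at least 20 nuclei was named after a cell type where at least 3 of its markers were detected in at least 0.1 of the nuclei at 0.25 or more of the highest cluster level, no other type reached 0.5 of its level, and the 10 leading genes did not hold more markers of another type. The markers were fixed before the data were examined. The rule that turns them into names was revised after the clusters were seen, and so were the separation of cerebellar granule neuron-like nuclei from the other neurons and the split of neurons into Slc17a6-led and inhibitory-like clusters. Slc17a6-led means that Slc17a6 reached 0.25 of its highest level with fewer than 3 inhibitory markers, so a name may rest on that transcript alone. Nuclei of clusters without a name entered no test.

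UMIs were summed per animal and set of nuclei and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, animal as block, R 4.3.3). Both sums of a pair come from the same animal. As a check, deviations of an animal's 2 sums from the group means were correlated across genes, and the lowest correlation was 0.400 for neurons against non-neuronal nuclei, 0.498 for the transmitter groups, 0.300 for Gfral-detected neurons and 0.108 for the Gfral-richest cluster. Fold changes are log2 values with a standard error (SE) computed from the fold change and its F statistic. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, over the listed genes for neurons, classes, transmitter groups and the Gfral-richest cluster, and over all tested genes except Gfral for Gfral-detected neurons. Classes were tested where every animal had at least 10 nuclei, each against the mean of the log levels of the other classes. Detected neurons had at least 1 Gfral UMI, and each was matched to 5 neurons of the same animal without one, by total UMIs. The Gfral-richest cluster is the neuron cluster of at least 50 nuclei, with nuclei in every animal, whose Gfral level averaged over animals was highest. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Shares of nuclei with a Gfral UMI were thinned to 1000 UMIs per nucleus, which left out no nucleus, and compared by an exact two-sided sign-flip test over animals. Levels are counts scaled to a common library total (CPM), computed here from the sums. Shares of a single library carry a 95% Wilson interval and CPM an exact Poisson one, and a count of 0 was given an upper limit of 3 counts. Both cover counting error only.

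Named genes follow a rule fixed before the data were examined. For listed genes these are the 10 with the largest fold in each direction (3 higher for each class) among those past the threshold and changed the same way in all 4 animals. For Gfral-detected neurons they are the 15 higher and 10 lower genes with the largest fold, with a mean of at least 10 CPM in the higher set. A fixed set of receptors and activity genes was added wherever tested. Of the genes named by this rule, 1 is not reported here, and no other gene takes its place. Tests were checked on simulated counts in which between 92 and 98 of the tested genes changed by each of 2 sizes. At a 2-fold change 71.4% were recovered for neurons against non-neuronal nuclei (13824 genes), 78.6% for the transmitter groups (12880 genes), 94.8% for Gfral-detected neurons (8838 genes) and 70.1% for the Gfral-richest cluster (11423 genes), and at a 4-fold change 97.9%, 96.9%, 100.0% and 95.7%. In the same order 14 of 177, 21 of 192, 7 of 192 and 7 of 163 calls were false, so the false share was above the 0.05 aimed at for neurons and for the transmitter groups. Simulated calls were adjusted over all genes, while the reported calls, except for Gfral-detected neurons, were adjusted over the listed genes. Few simulated genes changed, whereas 8120 of 14013 genes passed for neurons when adjusted over all genes. The rates of the reported tests may therefore differ.

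Alternatives set before the data were examined were UMI minimums of 500 and 2000, no profile test, no doublet removal, z-scores over all animals together, Leiden resolutions of 0.5 and 2.0, leaving out each replicate, no animal block, DESeq2 size factors, DESeq2 1.42.0, no low-count filter, other matchings of the undetected neurons, at least 2 Gfral UMIs, an estimated correlation and unthinned shares. A mitochondrial limit of 10%, granule-like nuclei counted as neurons, and matching within clusters without replicate 3 were chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.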

Results

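The series holds single-nucleus RNA profiles of the rat dorsal vagal complex, the brainstem area in which GFRAL, the receptor of the hormone GDF15, is known to be expressed. All 4 animals had received GDF15 at 100 µg/kg, 6 hours before tissue was taken, and 3 punches of area postrema and nucleus tractus solitarius were pooled per animal. Without an untreated group, the data describe which nuclei the tissue held and how they differed from each other within treated animals. The libraries held between 60481844 and 118399243 UMIs, and 26217 nuclei were kept, 4601, 6101, 6854 and 8661 in replicates 1, 2, 3 and 4.

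Neurons were the most frequent class on average, with 41.9% ± 18.4 of nuclei (SD, n = 4), followed by cerebellar granule neuron-like nuclei at 22.5% ± 33.5, oligodendrocyte-like nuclei at 15.2% ± 9.43, astrocyte-like nuclei at 5.51% ± 2.09 and oligodendrocyte precursor-like nuclei at 2.85% ± 1.46. Microglia-like nuclei made up 1.67% ± 1.16, choroid plexus-like nuclei 1.48% ± 1.01, fibroblast-like nuclei 0.704% ± 0.476, and committed oligodendrocyte precursor-like nuclei 0.617% ± 0.419. The rarest were endothelial-like nuclei at 0.573% ± 0.310, mural-like nuclei at 0.163% ± 0.105 and ependymal-like nuclei at 0.136% ± 0.116. Granule-like nuclei, named after clusters led by genes such as Gabra6, a GABA receptor subunit, and Cbln3, differed most between animals. They made up 1.02% and 0.705% of nuclei in replicates 1 and 2 and 16.8% in replicate 4, but 71.4% in replicate 3 (95% Wilson interval 70.4% to 72.5%). The 47 nuclei of replicate 1 held 0 Gabra6 UMIs of 137168, against 359, 878 and 688 CPM in replicates 2, 3 and 4, so their name rests on the cluster alone. With z-scores over all animals replicate 1 had 0 such nuclei. Without replicate 3 neurons averaged 50.9% ± 4.65 (n = 3) and granule-like nuclei 6.17% ± 9.20.

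Replicate 3 held 14.9% neurons, against 56.1%, 47.2% and 49.4% in replicates 1, 2 and 4. Of its 1019 neurons apart from granule-like nuclei, 980 lay in clusters made up mostly of replicate 3. These clusters were led by Gdpd4, Tfap2b and Kit, by Col28a1, or by Grm2 and Pax2. Parts of its oligodendrocyte-, astrocyte- and precursor-like nuclei also formed clusters of that library alone. For this reason the total count of genes of each comparison is given with and without replicate 3, while the counts of single lists include it. No cluster was named T cell-, Schwann cell- or erythroid-like, and the ependymal-like cluster held 0 nuclei of replicate 3. Names went to clusters of at least 20 nuclei, so these counts of 0 set no limit on the share of such nuclei. Clusters without a name held 6.68% ± 2.71 of nuclei.

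**Figure D1:**
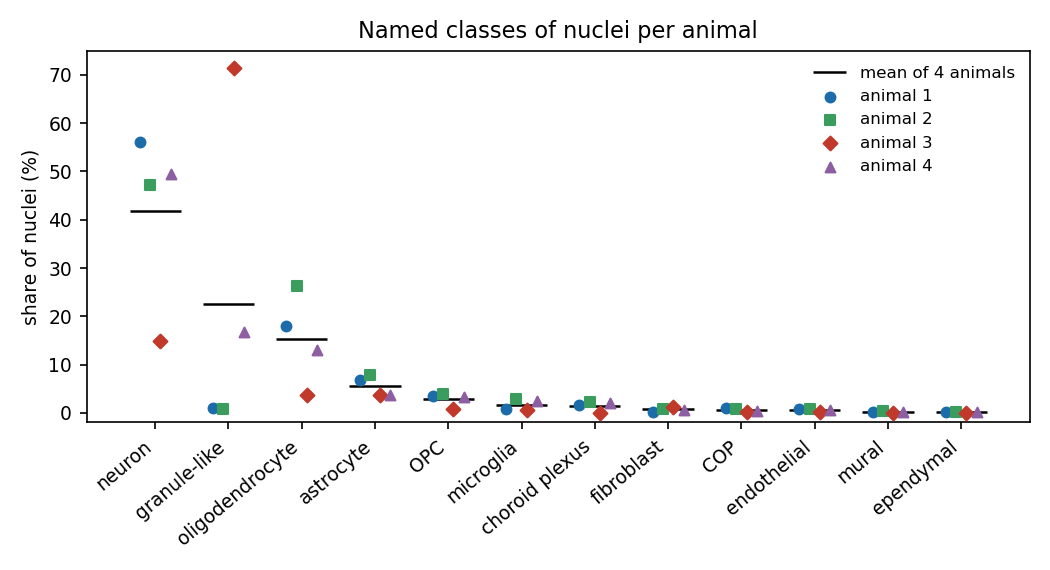
Share of nuclei (percent, vertical axis) in each named class, 1 symbol per animal and a line at the mean of 4 animals; OPC and COP are oligodendrocyte precursor-like and committed precursor-like nuclei. Replicate 3 stands apart, with 71.4% granule-like nuclei and 14.9% neurons.

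Transcripts of Gfral (ENSRNOG00000032063), the receptor gene, were more often detected in neurons than in other named nuclei. At an equal depth of 1000 UMIs per nucleus, 1.501% ± 0.758 of neurons (SD, n = 4) and 0.478% ± 0.193 of named non-neuronal nuclei held a Gfral UMI. Without thinning the shares were 3.75% ± 1.69 and 1.14% ± 0.526, at median depths of 3974, 4221, 3069 and 2668 UMIs in neurons and 2256, 2097, 2196.5 and 1564 in non-neuronal nuclei of replicates 1, 2, 3 and 4. Neurons had the higher share in 3 of 4 animals. In replicate 3 the share was 0.448% in neurons and 0.575% in non-neuronal nuclei, although 8 of its neurons, from a Gfral-rich cluster described below, held 18 Gfral UMIs, against 9 in its other neurons. Without replicate 3 the shares were 1.85% ± 0.351 and 0.446% ± 0.223 (n = 3). Granule-like nuclei held a Gfral UMI in 0.338% of cases in replicate 3 and 0.437% in replicate 4, and in 0 of 47 and 0 of 43 nuclei in replicates 1 and 2, which allows up to 6.38% and 6.98%.

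Shares of nuclei with a UMI of Calcr, Glp1r and Ret, which encode the calcitonin receptor, the GLP-1 receptor and the signalling partner of GFRAL, were higher in neurons in 4 of 4 animals. The thinned shares were 0.935% ± 0.597 against 0.146% ± 0.131 for Calcr, 0.292% ± 0.112 against 0.0672% ± 0.0222 for Glp1r and 3.52% ± 0.608 against 1.98% ± 0.399 for Ret. Exact two-sided sign-flip tests over the 4 animals gave p = 0.25 for Gfral and 0.125 for each of the other genes (0.25 and 0.167 after adjustment over the 4 genes). The smallest p that 4 animals allow is 0.125, so these tests could not pass 0.05.

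**Figure D2:**
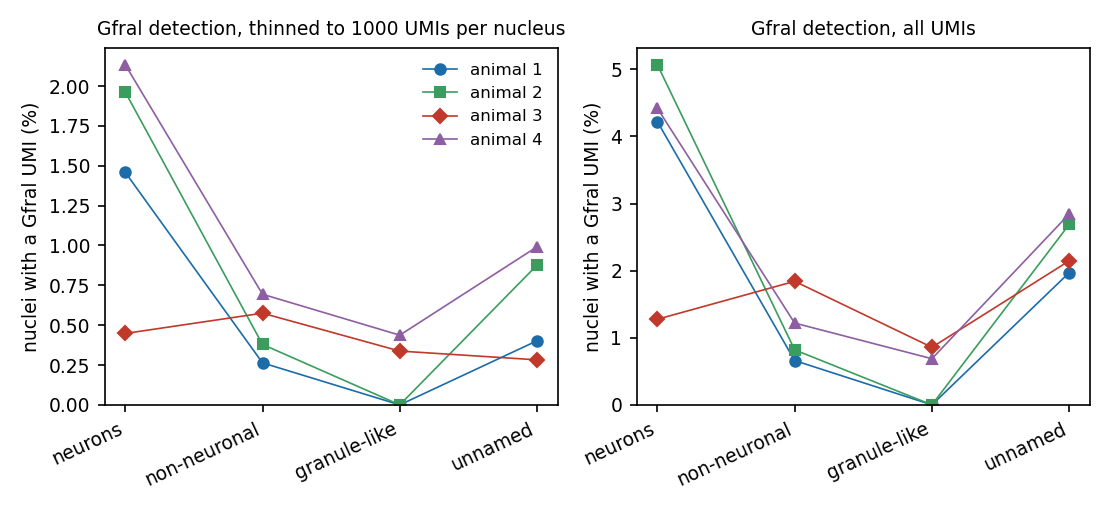
Percent of nuclei with at least 1 Gfral UMI (vertical axis) in neurons, named non-neuronal nuclei, granule-like nuclei and nuclei without a name, 1 line per animal, thinned to 1000 UMIs per nucleus (left) and with all UMIs (right). Thinned shares in neurons were 1.46%, 1.96%, 0.448% and 2.13% in replicates 1, 2, 3 and 4, and replicate 3 alone had a lower share in neurons than in non-neuronal nuclei.

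Neurons were first compared with the other named nuclei, leaving granule-like nuclei out of both sets, to see where receptors of hormones and peptides that act on feeding were expressed. Tacr1, the receptor of substance P, was higher in neurons by 3.39 ± 0.34 (log2 fold change ± SE, n = 4 animals; adjusted p = 0.000288), at 23.8 ± 12.6 CPM (SD) against 2.11 ± 0.889. The orexin receptor gene Hcrtr2 was higher by 3.01 ± 0.25, the dopamine receptor gene Drd2 by 2.94 ± 0.28 and the calcitonin receptor gene Calcr by 2.48 ± 0.42. Smaller differences were found for Gipr, for the receptor of glucose-dependent insulinotropic polypeptide (2.06 ± 0.31), the secretin receptor gene Sctr (1.94 ± 0.29) and Glp1r (1.81 ± 0.32). Among other genes, Dok6, an adaptor of receptor tyrosine kinases, was higher by 2.80 ± 0.14, the peptide gene Nmu by 2.06 ± 0.28 and the stress-response gene Trib3 by 1.79 ± 0.33. Each of these was higher in 4 of 4 animals, though 980 of the 1019 neurons of replicate 3 came from clusters made up mostly of that library. Gfral was higher by 1.95 ± 0.45 (adjusted p = 0.00877, 3 of 4 animals) and Ret by 0.58 ± 0.13 (0.00752, 4 of 4). Without replicate 2 both missed the threshold (Gfral 1.45, adjusted p = 0.0562; Ret 0.47, adjusted p = 0.052), as they did with granule-like nuclei counted as neurons (1.63, adjusted p = 0.0712; 0.20, adjusted p = 0.545). The activity-regulated gene Fos was higher by 0.96 ± 0.21 (0.00688), whereas Cck, Nr4a1, Ramp3 and Casr did not pass (0.46 ± 0.26, 0.40 ± 0.24, -0.51 ± 0.22 and 0.20 ± 0.33). Ramp3 passed without replicate 4 (-0.71, adjusted p = 0.0304), Cck without replicate 4 (0.81, 0.016) and at a minimum of 2000 UMIs (0.78, 0.00776), and with a mitochondrial limit of 10% Casr (0.90, 0.0118) and Nr4a1 (0.52, 0.0399). Nr4a1 also passed with granule-like nuclei counted as neurons (0.70, 0.0443), and Calcr missed the threshold without the animal block (2.26, 0.0609).

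Genes lower in neurons were led by receptors of inflammatory signals and of the TGF-beta family. Tgfbr2 was lower by -4.47 ± 0.21 (adjusted p = 1.47e-05), at 2.28 ± 0.879 CPM against 42.3 ± 12.5. The inhibitory SMAD gene Smad6 was lower by -4.06 ± 0.43, the membrane metalloproteinase gene Mmp14 by -3.52 ± 0.31, Il6r by -3.44 ± 0.24, Tlr4 by -3.30 ± 0.37 and the chemokine gene Cxcl12 by -3.26 ± 0.35. Il1r1 followed at -3.16 ± 0.39, Bmpr1b at -3.02 ± 0.32, Calcrl, which encodes a receptor of calcitonin gene-related peptide, at -3.02 ± 0.13 and the chemokine receptor gene Ackr3 at -2.81 ± 0.28, each in 4 of 4 animals. Of 15 tested genes of the cytokine and inflammatory list 13 were lower and 1 higher, with the same counts adjusted over the list alone and over all genes. Of 17 TGF-beta superfamily genes 9 were lower and 3 higher, with the same counts adjusted over the list alone and over all genes. Of 26 feeding and nausea receptors 13 were higher and 3 lower (13 and 3 adjusted over the list alone, 12 and 3 over all genes). The neuropeptide list had 8 higher and 2 lower of 22 (6 and 0 adjusted over the list alone), the activity-regulated list 5 and 6 of 18 and the MAPK feedback list 2 and 6 of 13 (2 and 7 adjusted over the list alone). The stress and glucocorticoid list had 2 and 4 of 15 and the GDF15 receptor family 3 and 2 of 6. Adjusted over all genes, 8120 of 14013 passed (3768 higher, 4352 lower), 81 of them listed, so most genes differed, listed or not. Adjusted over the listed genes, 82 of 132 passed, 37 higher and 45 lower. Without replicate 3 103 of 147 listed genes passed, among them all 82 in the same direction. The balance turned, with more genes higher than lower, without replicate 3 (54 and 49) or 4 (39 and 38), with a mitochondrial limit of 10% (53 and 45), with no low-count filter (51 and 44) and at a minimum of 2000 UMIs (42 and 38).

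Each of the 8 classes with at least 10 nuclei in every animal was then set against the others over 95 listed genes. Astrocyte-like nuclei had the BMP receptor gene Bmpr1b at 116 ± 33.5 CPM (SD, n = 4) against a mean of 1.73 CPM in the other classes (log2 fold change 6.60 ± 0.27 SE, adjusted p = 4.04e-20), with the transcription factor gene Etv4 higher by 4.20 ± 0.33 and Spry2, a feedback inhibitor of receptor tyrosine kinases, by 2.99 ± 0.39. Endothelial-like nuclei had the interleukin-1 receptor gene Il1r1 higher by 8.29 ± 0.46, Cxcl12 by 7.12 ± 0.27 and the NF-kappaB inhibitor gene Nfkbia by 3.46 ± 0.25. Microglia-like nuclei had Il6r higher by 6.18 ± 0.25, Tgfbr2 by 4.63 ± 0.30 and the interferon-gamma receptor gene Ifngr1 by 4.58 ± 0.21. Oligodendrocyte precursor-like nuclei had Etv4 higher by 4.68 ± 0.34, Calcrl by 4.46 ± 0.15 (516 ± 107 CPM against 51.3) and Nr4a1, an early activity gene, by 3.81 ± 0.60 on 39 UMIs.

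In committed oligodendrocyte precursor-like nuclei, the calcium-sensing receptor gene Casr was higher by 7.44 ± 0.45 (adjusted p = 3.29e-15), at 115 ± 20.1 CPM on 56 UMIs against 1.38 CPM. Gfra2 was higher there by 2.10 ± 0.50 and Smad7 by 1.60 ± 0.26. Oligodendrocyte-like nuclei had Ramp3, which encodes an accessory subunit of amylin receptors, higher by 1.57 ± 0.31, Smad7 by 1.30 ± 0.16 and Crem by 1.22 ± 0.16. Neurons had Tacr1 higher by 3.98 ± 0.41, Hcrtr2 by 3.13 ± 0.37 and the serotonin receptor gene Htr2c by 2.78 ± 0.31. Choroid plexus-like nuclei, with 1 nucleus in replicate 3, were not among the tested classes, and had Htr2c at 5952 CPM against 519 CPM in neurons of replicates 1, 2 and 4. Granule-like nuclei had Crhr1, for a receptor of corticotropin-releasing hormone, higher by 3.13 ± 0.36, Acvr1c by 2.71 ± 0.38 and Bdnf by 1.65 ± 0.28. Each of these genes was higher in 4 of 4 animals, but the granule-like set of replicate 1 is the 47 nuclei without a Gabra6 UMI. Without replicate 1 the values for granule-like nuclei were 3.16 for Crhr1, 2.72 for Acvr1c and 1.89 for Bdnf, all past the threshold. Leaving out 1 animal moved some of these folds by over 1.5 times, with each call kept. Without replicate 1 these were Etv4 in astrocyte- and oligodendrocyte precursor-like nuclei (5.07 and 5.38), Tgfbr2 in microglia-like nuclei (5.32) and Tacr1 in neurons (4.60), and without replicate 2 Bmpr1b in astrocyte-like nuclei (7.37) and Hcrtr2 in neurons (3.92). Without replicate 3 they were Etv4 in astrocyte-like nuclei (3.41) and Acvr1c in granule-like nuclei (3.45), and without replicate 4 Bmpr1b in astrocyte-like nuclei (7.69), Casr and Gfra2 in committed precursor-like nuclei (8.41 and 3.03), Il1r1 in endothelial-like nuclei (7.64) and Hcrtr2 in neurons (4.04). Casr was also called higher in neurons against the mean log level (2.03 ± 0.48), but at 4.73 CPM lay below the arithmetic mean of the other classes, 17.1 CPM, and the call was lost with z-scores over all animals (0.77, adjusted p = 0.0951), while without replicate 4 the value was 2.88. Ret was called higher in astrocyte-like nuclei (1.37 ± 0.27, adjusted p = 5.86e-05), at 39.2 CPM, and in neurons (0.91 ± 0.22, 0.000566), at 34.6 CPM. In granule-like nuclei it was called lower (-1.31 ± 0.35, 0.00288). Nr4a1 was also called higher in granule-like nuclei (3.03 ± 0.60, 0.000159), neurons (1.97 ± 0.71, 0.0163) and endothelial-like nuclei (2.68 ± 1.02, 0.0446, 8 UMIs), each in 3 of 4 animals. Fos was called higher in granule-like nuclei (1.31 ± 0.37, 0.00432) and neurons (0.86 ± 0.30, 0.0145), and Cck in neurons (0.57 ± 0.21, 0.0163). With DESeq2 the neuron calls of Nr4a1, Fos and Cck were lost (adjusted p = 0.0944, 0.0594 and 0.0578). Over all classes 161 calls were higher and 108 lower of 760, and without replicate 3 the counts were 155 and 103 of 744, with 233 calls shared. With a minimum of 2000 UMIs, where fewer tests could be made, 174 of 438 passed.

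To describe where the receptors lay among neurons, Slc17a6-led clusters were compared with inhibitory-like clusters. The name rests on the level of that glutamate transporter transcript, which need not be among a cluster's leading genes. Calcr was higher in Slc17a6-led neurons by 4.68 ± 0.34 (log2, SE, n = 4; adjusted p = 0.000246), at 31.0 ± 19.0 CPM (SD) against 1.11 ± 0.612. Casr was higher by 3.11 ± 0.31, the neurotrophin gene Bdnf by 3.01 ± 0.18, Gfral by 2.75 ± 0.26 (46.3 ± 23.6 against 6.85 ± 3.503 CPM) and Glp1r by 1.93 ± 0.29. These genes and Calcr were highest in the Gfral-rich cluster described below, which is 1 of the Slc17a6-led clusters. Over replicates 1, 2 and 4 it had Calcr at 185 CPM, Casr at 91.8, Bdnf at 181, Gfral at 353 and Glp1r at 33.2. The next neuron cluster had 35.5, 4.97, 49.6, 18.6 and 3.68 CPM. Whether the differences hold without that cluster was not tested. The peptide genes Pdyn, Adcyap1 and Nmu were higher by 1.94 ± 0.27, 1.84 ± 0.27 and 1.54 ± 0.21, Crhr1 by 1.48 ± 0.24 and Nr4a1 by 1.42 ± 0.21. Inhibitory-like neurons had higher Drd2 (-2.32 ± 0.13), Gipr (-1.80 ± 0.23), Ret (-1.42 ± 0.19), the cannabinoid receptor gene Cnr1 (-0.61 ± 0.08) and the chaperone gene Hspa5 (-0.31 ± 0.08), and higher peptide genes Pnoc (-2.27 ± 0.41), Sst (-1.50 ± 0.26) and Penk (-1.24 ± 0.14). Each held in 4 of 4 animals, but replicate 3 drew both groups mostly from clusters of its own, so its pair need not compare the same neurons. The 3 peptide calls were lost without replicate 3 (adjusted p = 0.0789 for Pnoc and 0.0583 for Sst and Penk). Pnoc was also lost without replicate 1 (0.115) and Sst without replicate 2 (0.0763), and Acvr2b (-0.63 ± 0.15) and Hspa5 when any of replicates 1, 2 or 4 was left out and with DESeq2 (adjusted p = 0.0554 and 0.0532). Acvr2b was also lost with no doublets removed (-0.52, 0.0863) and at minimums of 2000 and 500 UMIs (-0.41, 0.302; -0.58, 0.0799). Sst was further lost with no doublets removed (-1.11, 0.0686) and at a minimum of 2000 UMIs (-1.09, 0.147), and Pdyn (0.89, 0.0635) and Adcyap1 (0.98, 0.203) with a mitochondrial limit of 10%. Fos (0.73 ± 0.30), Cck (1.15 ± 0.34) and Ramp3 (0.23 ± 0.17) did not pass. Cck did pass with z-scores over all animals (1.28, adjusted p = 0.00773), with no doublets removed (1.29, 0.0172) and at minimums of 2000 and 500 UMIs (1.49, 0.0166; 1.33, 0.018).

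Of 124 listed genes 24 passed, 14 higher and 10 lower in Slc17a6-led neurons, and without replicate 3 50 of 131 passed, 21 of the 24 among them. With adjustment over all genes 226 of 13047 passed, 15 of them listed. Of 26 feeding and nausea receptors 6 were higher and 3 lower (7 and 4 adjusted over the list alone, 4 and 3 over all genes), and of 22 neuropeptide genes 5 were higher and 3 lower (9 and 3 adjusted over the list alone, 3 and 1 over all genes). The activity-regulated list had 2 higher of 17, the GDF15 receptor family 1 higher and 1 lower of 4 (1 and 2 adjusted over the list alone), and the cytokine list 1 lower of 11. The TGF-beta and stress lists had 1 lower of 16 and 1 lower of 15 (0 each adjusted over the list alone), and the MAPK list 0 of 13 by edgeR and by DESeq2 (4 at an unadjusted edgeR p under 0.05). In replicate 3, 199 of 220 Slc17a6-led and 781 of 798 inhibitory-like nuclei came from the clusters made up mostly of that library. Without the animal block 10 genes passed.

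Neurons with a Gfral UMI were compared with neurons of the same animal and depth without one, to describe what else nuclei with a Gfral count express. The detected sets held 109, 146, 13 and 189 nuclei, of which 31, 53, 4 and 65 lay in the Gfral-rich cluster described below. In the remaining neurons Gfral was at 9.02, 9.31, 2.45 and 13.6 CPM, against 6.47, 8.08, 6.84 and 8.04 CPM in barcodes of at most 100 UMIs. Barcodes of at least 200 and under 500 UMIs had 2.98, 8.16, 2.14 and 5.81 CPM, on 2, 30, 37 and 5 UMIs. A Gfral UMI alone thus does not mark a neuron as expressing the gene. In replicates 1 and 4 most barcodes of the plateau without a nucleus held 500 UMIs or more, and their Gfral level was not measured. In the Gfral-rich cluster 30.1% of nuclei held a Gfral UMI. Casr showed the largest difference, 5.22 ± 0.32 (log2, SE, n = 4; edgeR adjusted p = 2.84e-22), at 79.8 ± 38.0 CPM (SD) against 1.39 ± 1.39. Th, for tyrosine hydroxylase, was higher by 4.11 ± 0.23 (85.6 ± 34.6 against 4.53 ± 3.41 CPM), Gch1, whose product makes its cofactor, by 3.25 ± 0.30, Ddc, for aromatic amino acid decarboxylase, by 3.21 ± 0.14 and the noradrenaline transporter gene Slc6a2 by 3.04 ± 0.30. Calcr was higher by 2.82 ± 0.20, Bdnf by 2.45 ± 0.16, the nicotinic receptor subunit genes Chrna3 and Chrna5 by 2.42 ± 0.24 and 2.22 ± 0.26, Cck by 1.45 ± 0.19 and Ret by 0.70 ± 0.17. Micb (3.09 ± 0.20), Etv1 (2.52 ± 0.36), Bace2 (2.36 ± 0.29), Svil (2.32 ± 0.20) and the phospholipase gene Plce1 (2.20 ± 0.15) were also higher. Fos did not differ detectably (0.06 ± 0.34, adjusted p = 0.973, higher in 2 of 4 animals).

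Lower in Gfral-detected neurons were Slc6a5, the glycine transporter gene of inhibitory neurons (-0.84 ± 0.17), the extracellular matrix genes Vcan, Bcan and Gpc3 (-1.11 ± 0.20, -0.88 ± 0.19 and -1.26 ± 0.24), Arhgef26 (-1.84 ± 0.39), the channel gene Trpc4 (-1.03 ± 0.26), Notch2 (-0.98 ± 0.28), Bmper (-0.96 ± 0.18), Arhgap15 (-0.88 ± 0.19) and the phosphodiesterase gene Pde1c (-0.83 ± 0.18). All genes named here except Fos held their direction in 4 of 4 animals. With undetected neurons taken from the same cluster, Casr was higher by 3.16 ± 0.25, Th by 2.68 ± 0.18, Ddc by 1.22 ± 0.10, Calcr by 1.23 ± 0.17 and Slc6a2 by 0.75 ± 0.21, and Vcan (-0.51 ± 0.22), Bcan (-0.65 ± 0.20), Trpc4 (-0.80 ± 0.29), Notch2 (-0.46 ± 0.31) and Arhgap15 (-0.28 ± 0.21) no longer passed, though Bcan and Trpc4 kept most of their fold. With that matching and without replicate 3, Slc6a2 (0.67, adjusted p = 0.172), Bace2 (0.81, 0.0593) and Arhgef26 (-0.67, 0.722) did not pass either. The Gfral-rich cluster ran out of undetected neurons, so that matching left part of the difference in cluster mix in place. Etv1 is also a marker of granule neurons, and lost its call in 9 alternatives, among them without replicate 1 (2.43, adjusted p = 0.143), with at least 2 Gfral UMIs (3.69, 0.069), against all undetected neurons (2.09, 0.37) and with a mitochondrial limit of 10% (1.73, 0.476). With DESeq2 the calls of Ret, Slc6a5, Arhgef26, Trpc4, Notch2, Arhgap15 and Pde1c were lost, at adjusted p from 0.0722 for Slc6a5 to 0.424 for Notch2. Without the animal block these 7, Etv1, Cck, Vcan, Bcan and Bmper were lost. Without replicate 2 Cck (0.82, adjusted p = 0.0677), Ret (0.77, 0.0638), Arhgap15 (-0.78, 0.0568), Notch2 (-0.96, 0.184), Pde1c (-0.73, 0.202) and Trpc4 (-0.80, 0.417) did not pass, nor without replicate 4 did Ret (0.61, 0.139) and Notch2 (-0.85, 0.366), nor with a mitochondrial limit of 10% Trpc4 (-0.71, 0.0771) and Notch2 (-0.53, 0.228). Casr was at 4.63 without replicate 2.

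**Figure D3:**
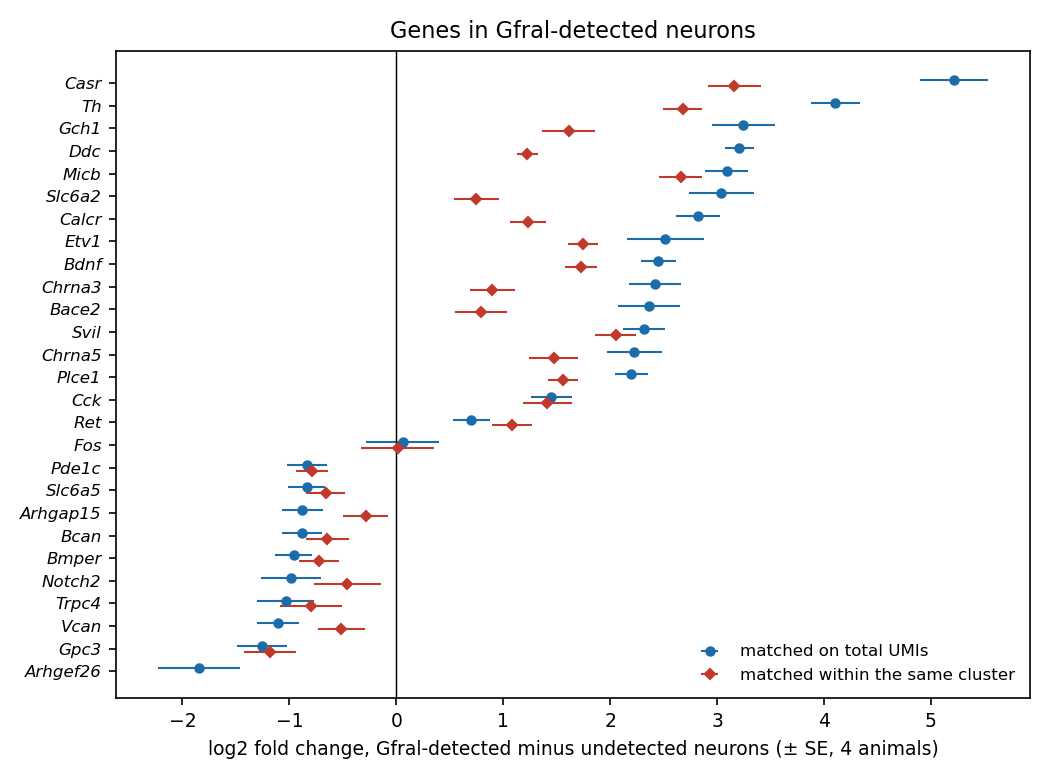
Log2 fold change (horizontal axis, ± SE, 4 animals) of the named genes in Gfral-detected minus undetected neurons, with undetected neurons matched on total UMIs (blue circles) or also within the same cluster (red diamonds). Casr lies at 5.22 and 3.16 and Th at 4.11 and 2.68. Arhgef26 was not tested within clusters over the 4 animals.

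In total 347 of 9022 genes passed, 211 higher and 136 lower, and without replicate 3 463 of 11254, with 338 of the 347 among them. The count was 142 without replicate 2, 209 without replicate 4, 44 without the animal block (43 higher, 1 lower) and 92 with DESeq2 (76 and 16). More genes were lower than higher with at least 2 Gfral UMIs (254 higher, 277 lower) and with no low-count filter (194 and 216). Of the 68 listed genes tested 15 passed, and 21 did when adjusted over the listed genes alone (16 higher and 5 lower). Among 12 feeding and nausea receptors 3 were higher (adjusted p = 0.00869 for the list by camera; adjusted p = 0.257 with an estimated correlation). Among 14 neuropeptide genes 4 were higher and 2 lower (0.00608; adjusted p = 0.173 with an estimated correlation). Among 6 activity-regulated genes 2 were higher (0.00108; adjusted p = 0.173 with an estimated correlation) and among 8 MAPK feedback genes 3 were higher (0.0179; adjusted p = 0.257 with an estimated correlation). The tests of these lists pointed upwards, while the median log2 fold change was -0.05 for the receptors and -0.04 for the neuropeptides. Adjusted over the list alone, the counts were 3 higher and 1 lower, 6 and 4, 2 and 1, and 4 and 1. The GDF15 receptor family had 1 higher of 2 (1 and 1 adjusted over the list alone), and the stress, cytokine and TGF-beta lists had 0 of 12, 0 of 4 and 0 of 10 by edgeR and by DESeq2 (0, 0 and 1 at an unadjusted edgeR p under 0.05), with camera adjusted p of 0.679, 0.976 and 0.429.

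The neuron cluster richest in Gfral held 508 nuclei, 126, 169, 8 and 205 per animal. It was led by Ddc, Slc6a2, Chrna3, Olr59 and Th, with Gfral at 371 CPM. It was compared with all other neurons. The 8 nuclei of replicate 3 held 34747 UMIs, so that 3 UMIs made 86.3 CPM in that animal, which weighs on the means below. Casr was higher by 6.54 ± 0.28 (log2, SE, n = 4; adjusted p = 1.89e-54), at 155 ± 127 CPM (SD) against 0.946 ± 0.627. Sctr was higher by 4.97 ± 0.19, Glp1r by 4.41 ± 0.34 (46.5 ± 26.7 against 1.51 ± 0.429 CPM), Calcr by 4.23 ± 0.17 and Ramp3 by 1.94 ± 0.28. The peptide genes Nts, Nmu and Cck were higher by 4.05 ± 0.40, 2.31 ± 0.18 and 2.01 ± 0.25, Bdnf by 3.01 ± 0.15 and the kinase feedback gene Spry4 by 1.86 ± 0.35. Ret (0.95 ± 0.18) and Nr4a1 (1.497 ± 0.34) were also higher, and Gipr was higher by 1.93 ± 0.26 in 3 of 4 animals, with 0 counts in the 8 nuclei of replicate 3. Fos was not detectably different (-0.04 ± 0.34, adjusted p = 0.957).

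Lower in this cluster were Hcrtr2 (-3.79 ± 0.43), Htr2c (-2.73 ± 0.16), the glucocorticoid-induced genes Zbtb16 and Sgk1 (-2.69 ± 0.41 and -1.95 ± 0.19), the opioid receptor gene Oprm1 (-1.81 ± 0.24), Calcrl (-1.76 ± 0.53) and the peptide genes Pnoc and Gal (-2.23 ± 0.34 and -1.52 ± 0.25). Nr4a3 (-1.54 ± 0.59, 5 UMIs in the cluster) and Grp (-1.49 ± 0.56, 6 UMIs) were called lower, but rested on where the cluster ended. At a resolution of 0.5, where it held 624 nuclei, Nr4a3 was higher by 0.93 (adjusted p = 0.0131) and Grp at 0.041 (0.934). Grp lost its call without replicate 1 (-1.06, 0.15) or 4 (-0.97, 0.197). Nr4a3 lost it without replicate 2 (-0.84, 0.422) and Calcrl without replicate 1 (-1.33, 0.0511) or 2 (-1.32, 0.0899). Zbtb16 also rested on the extent of the cluster, at -0.50 (0.08) at resolution 0.5, -0.49 (0.0751) at 2.0 and -0.53 (0.0525) with no doublets removed, and so did Calcrl, at -0.63 (0.163), -0.84 (0.0613) and -0.70 (0.121). Calcrl was also lost without the profile test (-0.93, 0.05002). Sgk1 was lost at resolution 0.5 (-1.51, 0.101), with z-scores over all animals (-1.49, 0.144), without the profile test (-1.48, 0.108) and at a minimum of 500 UMIs (-1.55, 0.136). Without the animal block Nr4a1 (1.09, 0.107), Gal (-1.22, 0.437), Calcrl (-1.65, 0.0686), Nr4a3 and Grp did not pass, nor did Nr4a3 and Grp with DESeq2. Without replicate 4 Calcrl was at -3.77, and without replicate 1 Hcrtr2 at -4.63. Of 105 listed genes 52 passed, 28 higher and 24 lower, and without replicate 3 57 of 134, with 49 of the 52 among them. With adjustment over all genes 2265 of 11715 passed, 46 of them listed. Of 21 feeding and nausea receptors 9 were higher and 6 lower, with the same counts adjusted over the list alone and 7 and 6 over all genes.

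**Figure D4:**
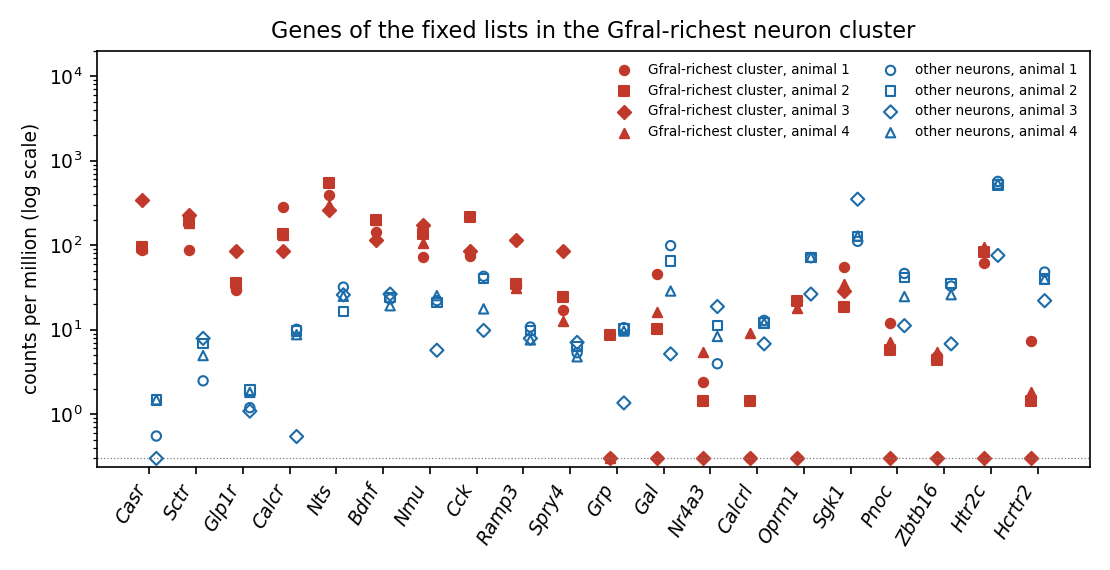
CPM (vertical axis, log scale) of the 20 named genes in the Gfral-richest cluster (filled symbols) and in the other neurons (open symbols), 1 symbol shape per animal; values under 0.3 are drawn at 0.3, the dotted line. In the cluster Casr lay between 87.6 and 346 CPM, and in other neurons between 0.272 and 1.48 CPM.

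Of 19 neuropeptide genes 5 were higher and 6 lower in the cluster, of 16 activity-regulated genes 4 and 2, and of 10 MAPK feedback genes 4 and 2. Of 14 stress and glucocorticoid genes 1 and 2, of 8 cytokine genes 1 and 2 and of 3 genes of the GDF15 receptor family 1 and 1, with the same counts adjusted over the list alone. Of 14 TGF-beta superfamily genes 3 were higher and 3 lower (2 and 3 adjusted over the list alone).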

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

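The tests of barcode sharing, of reads from outside the gene and of matching within clusters were set before their results were seen, and the other tests in this part were chosen only after the result was seen. All animals belong to 1 group, so no biological explanation was tested.

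Replicate 3 stood apart in most of the values below. Of 123 sets of 4 values, 22 had 1 animal far from the others, 20 of them replicate 3, where chance gives about 1 in 20 sets, or 6.15. In neurons Tacr1 was lowest in replicate 3, at 5.13 CPM against 27.4 to 31.9 in the other animals, and so was Dok6, at 323 CPM against 683 to 748. In Slc17a6-led neurons replicate 3 was highest for Crhr1, at 37.6 CPM against 10.5 to 12.8, for Nr4a1, at 40.6 against 8.46 to 11.6, and for Fos, at 56.4 against 14.4 to 19.5, while Adcyap1 was highest in replicate 2, at 76.9 against 54.4 to 57.6. In inhibitory-like neurons Acvr2b was lowest in replicate 3, at 8.17 CPM against 14.999 to 16.3, and Cnr1 highest, at 199 against 82.3 to 89.7.

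In Gfral-detected neurons Slc6a2 was highest in replicate 3, at 134 CPM against 40.7 to 42.4. In their matched undetected neurons replicate 3 was highest for Arhgef26, at 148 CPM against 8.75 to 31.6, for Vcan, at 302 against 39.8 to 70.6, and for Bcan, at 218 against 45.7 to 63.8. In the Gfral-richest cluster, of which replicate 3 held 8 nuclei, that animal was highest for Casr, at 346 CPM against 87.6 to 95.5, for Glp1r, at 86.4 against 29.2 to 36.2, for Ramp3, at 115 against 30.8 to 34.7, and for Spry4, at 86.4 against 12.7 to 24.6, while Cck was highest in replicate 2, at 217 against 75.4 to 86.9. Those 8 nuclei held 34747 UMIs, and Casr rested on 12 (Poisson interval 178 to 603 CPM). A count of 3 UMIs there, as for Calcr, gave 86.3 CPM with an interval of 17.8 to 252 CPM. That interval holds the Glp1r values of the other animals, so counting error alone may set Glp1r apart. In the other neurons replicate 3 was lowest for Htr2c, at 75.7 CPM against 515 to 569, for Oprm1, at 26.4 against 71.2 to 72.0, for Calcrl, at 6.81 against 12.03 to 12.9, and for Grp, at 1.36 against 9.65 to 10.6, and highest for Sgk1, at 350.4 against 111 to 128.

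Nuclei of clusters without a name entered no comparison, and 42 of these 1695 nuclei, 2.48%, held a Gfral UMI, a signal in data that no comparison uses. The shares were 1.97%, 2.69%, 2.15% and 2.84% in replicates 1, 2, 3 and 4, against 0.661%, 0.820%, 1.84% and 1.22% in named non-neuronal nuclei. Median depths were 4047, 3849, 6901 and 2795 UMIs against 2256, 2097, 2196.5 and 1564, so the unnamed nuclei were deeper. Thinned to 1000 UMIs per nucleus the shares were 0.402%, 0.877%, 0.283% and 0.992% against 0.264%, 0.379%, 0.575% and 0.694%.

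The first pattern weighed is the make-up of replicate 3, and a pool in which area postrema and solitary tract tissue made up a large part stays open: with z-scores over all animals, 2.15% of the neurons of replicate 3, granule-like nuclei included, lay in clusters that each held at least 1% of the neurons of replicates 1, 2 and 4, between the bounds of 2% and 10%, with 100% of its oligodendrocyte-like but 17.9% of its astrocyte-like nuclei in such clusters of their class. The share was 0.490% in the main clustering, 4.53% with the 10% mitochondrial limit and 0.440% to 1.19% in the other settings, but there only 5.58% to 16.1% of its oligodendrocyte-like nuclei lay in such clusters, so those clusters parted libraries and decide nothing. A library of another tissue without area postrema nuclei is argued against by the 8 nuclei of replicate 3 in the Gfral-richest cluster. Reads assigned to the wrong library would repeat barcodes, and 0% of the 92 nuclei of replicate 3 in clusters of the other libraries shared a barcode with a nucleus of the same cluster elsewhere. A punch that held mostly cerebellum, and a wrong label together with nuclei carried over between samples at preparation, were not told apart by any test and stay open.

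The next pattern is Gfral counts in nuclei that are not Gfral neurons, and free RNA of Gfral neurons was neither supported nor excluded in named non-neuronal nuclei of replicates 1, 2 and 4, where Gfral UMIs per Calcr UMI were 0.524, 4.17 and 2.57 against 1.48, 2 and 2 in barcodes of at most 100 UMIs, and per Th UMI 0.647, 1.79 and 2.57 against 0.660, 1.07 and 0.720. Ratios departed both ways, and the lowest Fisher's exact p of the 6 comparisons was 0.000748 (Th in replicate 4), which is 1 library only. Barcodes of at most 100 UMIs are also an uncertain measure of free RNA. In replicates 1, 2, 3 and 4 they held the granule marker Gabra6 at 22.3, 22.5, 296 and 63.0 CPM. Barcodes of at least 200 and under 500 UMIs held it at 2.98, 1.90, 650 and 80.2 CPM (2 and 7 UMIs in replicates 1 and 2). In granule-like nuclei of replicate 3 there were 44 Gfral UMIs and 1 Calcr UMI, against 19 and 7 in barcodes of at most 100 UMIs of that library (Fisher's exact two-sided p = 0.00293), 37 and 5 in barcodes of at least 200 and under 500 UMIs (p = 0.102) and 18 and 3 in the Gfral-richest cluster (p = 0.0913). The outcome thus depends on the barcodes taken for free RNA. With barcodes of replicate 3 ranked by UMIs, the plateau without a nucleus ran from 463 UMIs at rank 20901 to 279 at rank 64578. Barcodes of at least 200 and under 500 UMIs are thus the closer measure, and against them no departure was found. As these held only 5 Calcr UMIs, free RNA stays open there too. Reads from outside the gene, or low expression in many cells, stay open: Gfral was at 6.84 CPM (4.12 to 10.7) in barcodes of at most 100 UMIs of replicate 3 and 3.24 CPM (2.36 to 4.36) in its granule-like nuclei, the outcome set beforehand as speaking against it, but at 2.14 CPM (1.51 to 2.95) in its barcodes of at least 200 and under 500 UMIs, and RNA freed from those same nuclei would also reach such barcodes, so that bound decided nothing.

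The last pattern is the set of genes higher in Gfral-detected neurons. Matching within clusters was meant to remove the difference if more nuclei from 1 cluster among the detected neurons were the whole cause. With that matching the median log2 fold change of 210 higher genes was 0.48, against 0.69 without it, and 208 stayed above 0. However, the Gfral-rich cluster ran out of undetected neurons. Matched sets held 485, 581, 45 and 760 undetected neurons in replicates 1, 2, 3 and 4, against 545, 730, 65 and 945 without that matching. The cluster mix thus still differed, and the genes had been chosen with the same detected neurons. The test therefore cannot decide whether the mix of clusters was the whole cause. Of the 210 genes 121 passed within clusters. Part or all of the difference may follow the mix of clusters, and Slc6a2 moved from 3.04 to 0.75 and Ddc from 3.21 to 1.22. Undetected neurons were matched on total UMIs, so depth was not tested as an explanation. Differences between cell types within a cluster stay open.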

How the results depend on the processing

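The mitochondrial limit of 10%, granule-like nuclei counted as neurons, and matching within clusters without replicate 3 were tests chosen only after the result was seen. The replicate block pairs the sums of each animal: without it 44 genes passed for Gfral-detected neurons (main count 347) and 10 for Slc17a6-led against inhibitory-like neurons (main count 24), while the counts for neurons (62), classes (235) and the Gfral-richest cluster (35) stayed within 1.5 times of the main ones. For Gfral-detected neurons 92 genes passed with DESeq2, 531 with at least 2 Gfral UMIs, where 4807 genes were tested, 219 with matching within the same cluster and 196 with that matching without replicate 3. Leaving out 1 replicate gave between 142 and 463 genes for that comparison and between 16 and 50 for the transmitter groups, where z-scores over all animals together gave 38. Classes had 174 calls at a minimum of 2000 UMIs, where 438 were tested. The Gfral share difference between neurons and non-neuronal nuclei was 2.61 percentage points without thinning.

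Shares of small classes followed the clustering, as a class without a cluster of its own has a share of 0. Endothelial- and mural-like nuclei were at 0% with a mitochondrial limit of 10%, with no doublets removed, at resolution 0.5 and at a minimum of 2000 UMIs. Microglia-like nuclei were at 0% at 2000 UMIs and 3.12% with the 10% limit, where ependymal-like nuclei were at 0.451%.

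For named genes, 442 of 455 values in neurons, 898 of 1004 in classes, 317 of 352 in the transmitter groups, 463 of 518 for Gfral-detected neurons and 339 of 382 for the Gfral-richest cluster kept their direction and their side of the threshold. In the Gfral-richest cluster Nr4a3 turned to 0.86 with z-scores over all animals, 0.47 without the profile test, 0.92 with no doublets removed, 0.93 at resolutions of 0.5 and 2.0 and 0.45 at a minimum of 500 UMIs, and Grp to 0.14 with no doublets removed, 0.041 at resolution 0.5 and 0.021 at 2.0. These settings gave a larger cluster of between 561 and 642 nuclei. Nr4a1 in oligodendrocyte-like nuclei, not called in the main test (0.15), was -1.32 with DESeq2 and -1.003 with the 10% limit. Beyond tested genes, animals and cluster size, the cause was not tested.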

Other observations

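The tests on other splits of the samples were chosen only after the result was seen. The genes in this paragraph and the next were chosen after their values were seen, and levels are means over replicates 1, 2 and 4 (± SD, n = 3). Choroid plexus-like nuclei had Htr2c, a serotonin receptor gene, at 5952 ± 363 CPM, against 519 ± 29.4 in neurons, and Gdf15, the gene of the injected hormone, at 53.6 ± 10.2 CPM, with mural-like nuclei next at 16.2 on 1 UMI. They also had the chaperone gene Hspa5 at 926 ± 289 CPM and Crhr2, a receptor gene of the corticotropin-releasing hormone family, at 22.9 ± 2.80. Oligodendrocyte precursor-like nuclei had both Calcrl and Ramp1, whose products form the receptor of calcitonin gene-related peptide, at 554 ± 91.9 and 268 ± 125 CPM. An unnamed cluster with Wt1 had the stress-response gene Ddit4 at 144 ± 32.5 CPM and the cytokine receptor gene Lifr at 208 ± 127.

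Among neurons, Gipr was highest in an inhibitory-like cluster led by Rbm44, Defb10 and Col14a1, at 136 ± 37.3 CPM, with the Gfral-richest cluster next at 39.9. That inhibitory-like cluster also had Penk at 1288 ± 501 CPM, Cartpt at 509 ± 303, Drd2 at 106 ± 15.7 and Oprm1 at 154 ± 28.4. Calca and Calcb, which encode calcitonin gene-related peptides, were highest in a cluster led by Nefm, Spp1 and Nefl, at 1878 ± 1381 and 203 ± 128 CPM. These rested on 483 and 58 UMIs in 96 nuclei, and the next neuron cluster had 274 and 132 CPM. Single UMIs weigh heavily there, as Arc averaged 31.9 CPM on 1 UMI, so the rank of Calcb is uncertain. A cluster led by Lmx1b had Gal at 191 ± 122 CPM and Gcg, the gene of glucagon-like peptides, at 30.2 ± 36.4. The Gfral-richest cluster had Glp1r at 33.2 ± 3.62 CPM, with the next cluster at 3.68, Crhr2 at 28.6 ± 15.4 and Nts at 411 ± 121.

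Each animal gives 1 sum to either side of a paired comparison, and 8 splits of the 8 sums part every pair, the real one included, while the other 27 put both sums of at least 1 animal on the same side. With 8 splits a share under 0.05 cannot be reached. For neurons against non-neuronal nuclei the real split gave 82 genes and the highest other 0, for Slc17a6-led against inhibitory-like neurons 24 and 14, for Gfral-detected neurons 347 and 144, and for the Gfral-richest cluster 52 and 22, so in each case 1 split, the real one, gave as many genes. For the cell classes, where class names were drawn at random within each animal, 1 of 25 labellings, the real one, gave as many calls, 269 against at most 26. Neurons, classes, transmitter groups and the Gfral-richest cluster were formed by clustering the same nuclei, so their sums differ by construction and other splits do not show whether chance can be excluded.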
